A study of Mus musculus with 12 samples.

How the data were processed

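ATAC-seq peak lists of 12 libraries in 6 groups were used, 1 list per group, named in the labels for both libraries of the group. The deposited files hold chromosome, start and end of each peak and no other value, and per the labels nothing states how the 2 libraries were combined. The submitters' processing notes name BWA without a version, MACS2 2.0 and STAR 2.5, with no role or order for each, and list the build mm9. The coordinates were tested against gene positions of GRCm38: 50.6% to 68.0% of peaks lay within 1000 bases of a gene start or end, against 4.66% to 7.80% after shifting the peaks, so GRCm38 was used.

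Rows on chromosomes 18 and 19 were repeated. Exact duplicates numbered 2530, 2529, 510, 214, 173 and 115 in the lists at 0, 24, 40, 56, 72 and 120 h without E2, and all lay on these chromosomes, as did all overlapping rows and all intervals over 10000 bases. Those intervals and the duplicates were left out and overlapping rows were merged. Depth was not given in the sources used here, so no precision beyond counting error over regions can be stated.

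Lists were compared by overlap of 1 base or more. Regions were the union of the 6 lists. Lost, gained and kept regions were defined by continuous E2 and 120 h alone. Shares have 95% Wilson intervals, and chance overlap came from 100 random placements. Fisher's exact tests were two-sided, with Benjamini-Hochberg adjustment over the 10 gene lists in each direction at 0.05. Lists were also set against 10000 random gene lists with the same numbers of regions per gene. A shuffle of classes within 10 width classes and gene boundary class was added after seeing the data. The tests compare regions and give no p-value between samples, because each group had 1 list.

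Choices fixed before the data were examined were kept except for these. The gene table gives no strand, so a region was assigned to the protein-coding gene it overlaps or whose start or end lies nearest within 50000 bases, and a gene boundary (start or end, 1000 bases) replaced the promoter. Exon and intron shares were left out. Motif content was not analysed here, because no genome sequence was used here. Peak strength was read from width, as no score was given.

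Genes were named by a rule fixed in advance. For each list it took up to 4 genes with the most lost regions, 4 with the most gained and 2 with the most kept, with ties broken by summed width. It added the 10 genes with the most lost and the 10 with the most gained regions, the 3 widest regions of each class, and Hoxa9, Lyz2, Meis1, Cebpa, Cebpe, Spi1, Gfi1 and Irf8. One gene taken by this rule is not reported here.

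Alternatives covered the overlap rule (50% reciprocal, or within 200 bases), list length, peak width, chromosomes, the boundary window (500 or 2500 bases) and the assignment distance (20000 or 100000 bases). The functions for merging, overlap, region classes, single switches and the exact test of gene lists were tested on simulated data with known classes. Those for gene assignment, gene boundary tests, random gene lists, shuffles and random placements were not. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used, with fixed seeds.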

Results

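Chromatin accessibility was measured by ATAC-seq in murine ER-Hoxa9 Lys-GFP cells. These are myeloid progenitors held immature by a fusion of Hoxa9 to the estrogen receptor, which needs estradiol (E2), and they carry a GFP reporter for lysozyme expression. The series held 12 libraries in 6 groups of 2, and 1 peak list was deposited per group. One group was kept in E2 and another went 120 h without it. The other 4 groups were deprived of E2 for 24, 40, 56 or 72 h and then had it back for 96, 80, 64 or 48 h. After cleaning, the lists held 13165 peaks in continuous E2, then 11465, 9940, 8989 and 9581 peaks after 24, 40, 56 and 72 h of withdrawal with add-back, and 7987 peaks at 120 h. The peak lists gave no score, count or depth, so depth was unknown and there were no replicate values. Intervals covered counting error over regions only, and p-values compared groups of regions, not samples. Longer withdrawal always came with shorter add-back, so the pair of durations was compared as 1 variable.

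The first comparison asked which regions differed between continuous E2 and 120 h without E2. Of the 6663 regions called in E2 but not at 120 h, termed lost, 48 lay at progenitor genes of a list fixed in advance. Meis1, a Hoxa9 cofactor, had 5 lost regions and 1 kept region. Cd34, a stem cell surface marker, had 4 lost and 1 kept, and Flt3, a progenitor cytokine receptor, had 4 lost and 1 gained. Regions called at 120 h but not in E2, termed gained, lay at Csf3r, the G-CSF receptor, with 2, and at the neutrophil genes Fpr1, Itgb2l and Lyz1 with 1 each. Alox5, which makes leukotrienes, had 2 gained regions.

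Of the continuous-E2 peaks, 49.4% overlapped a 120 h peak (95% Wilson interval 48.5 to 50.2), and of the 120 h peaks 81.6% overlapped a continuous-E2 peak (80.8 to 82.5). Peaks placed at random within their chromosomes overlapped in 0.487% and 0.810%. The union of the 6 lists held 16028 regions, of which 6502 were kept, 6663 lost, 1467 gained and 1396 in neither end point. When all lists were shortened to the 7987 widest peaks, 38.5% of continuous-E2 peaks and 38.3% of 120 h peaks lacked a partner, 2 shares that equal lengths make about equal by construction. The share of 120 h peaks without a partner, 18.4% here, was 31.7% under 50% reciprocal overlap and 11.6% without narrow peaks. Lost peaks were narrower than kept ones, with median widths of 720 and 935 bases, and gained peaks had a median of 443.5 against 603 bases.

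Of the 32 progenitor and Hoxa9-associated genes, 25 had an assigned region and 23 had a lost one. The list had 48 lost, 3 gained and 10 kept regions, a lost share of 82.8% against 48.5% at other genes (odds ratio 5.09, 95% interval 2.58 to 10.1, Fisher's exact adjusted p = 9.7e-07). Random gene lists with the same numbers of regions had a median lost share of 65.5%, and the list stood at percentile 99.8 of them. Of 10000 such lists, 21 reached its share. The exact tests of gene lists, here and below, take regions of the same gene as independent. Their p-values can therefore be too small and their intervals too narrow. Besides Meis1, Cd34 and Flt3, the list included Runx1 with 3 lost, 1 gained and 2 kept regions, Bcl2 with 3 lost and 1 gained, and Cdk6 with 3 lost and 2 kept. With regions at gene boundaries left out, the odds ratio was 2.29 and the exact adjusted p was 0.283, which ended the call. No region was assigned to Hoxa9.

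Of 30 late neutrophil genes, 19 had a region and 10 had a gained one, giving 10 gained, 9 lost and 7 kept regions (odds ratio of gained against kept 6.74, interval 2.56 to 17.7, exact adjusted p = 0.00161). The gained regions included those of Fpr1, a formyl peptide receptor, Itgb2l and Lyz1. Anxa1 had 1 gained and 2 lost regions, and Cxcr4 had 1 gained, 1 lost and 1 kept. Cebpb had 2 lost regions and Trem1 had 1, and neither had a gained one. No region was assigned to Lyz2, and the Lyz1 region was the only one within 50000 bases of it. Primary granule and promyelocyte genes had 5 gained, 6 lost and 3 kept regions (odds ratio 7.83, exact adjusted p = 0.0195), with gained regions at Csf3r, Fcnb, Ms4a3 and Cebpa. The 6 lost regions included single ones at the granule protein genes Mpo, Prtn3 and Ctsg. Another lay at the boundary of Cebpa, while the gained region of Cebpa lay 29079 bases away. The gained call of this list ended with lists of equal length (odds ratio 5.19, exact adjusted p = 0.145) and without chromosomes 18 and 19 (6.30, 0.0522), the latter chosen after seeing the data.

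Phagocyte function genes had 10 gained, 6 lost and 14 kept regions (odds ratio 3.36, exact adjusted p = 0.0195), including gained regions at Ncf1 and Ncf4, subunits of the NADPH oxidase, and Tlr2. Monocyte and macrophage genes had 5 gained, 8 lost and 4 kept regions (odds ratio 5.87, exact adjusted p = 0.0282). Gained regions lay at Ly6c2, Adgre1, Cx3cr1 and Cd68, and lost ones at Csf1r, Irf8 and also Adgre1. Lost against kept regions of these 4 lists did not pass the test, with exact adjusted p-values of 0.341 to 0.621. Among shuffles of gained and kept regions matched on width and gene boundary, 2445 of 10000 reached the share of the phagocyte list and 1234 that of the monocyte list, against 295 for primary granule and 3 for late neutrophil genes. Leaving out gene boundary regions ended the gained calls of all 4 lists, with exact adjusted p-values of 0.483 for late neutrophil, primary granule and phagocyte genes and 0.701 for monocyte genes. The odds ratios were then 3.11, 7.47, 2.08 and 2.80, so that of primary granule genes stayed about as large, on 4 gained and 1 kept regions. In the same setting, phagocyte genes had fewer lost regions than other genes (3 lost and 9 kept, odds ratio 0.126, exact adjusted p = 0.00851).

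Cell cycle genes had 7 lost, 4 gained and 15 kept regions, and housekeeping genes 7 lost, 1 gained and 14 kept. Neither list passed the test in either direction. Boundary regions of Mki67, E2f1, Irf8, Eef1a1 and Hprt were called in every list except that of 120 h. Lists for other lineages had few regions. Erythroid and megakaryocyte genes had 3 lost and 1 kept, lymphoid genes 5 lost, 1 gained and 2 kept, and mast cell, basophil and eosinophil genes 4 lost and 1 gained, and none passed the test. The lymphoid factor gene Ebf1 held 3 of the lost regions.

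**Figure D1:**
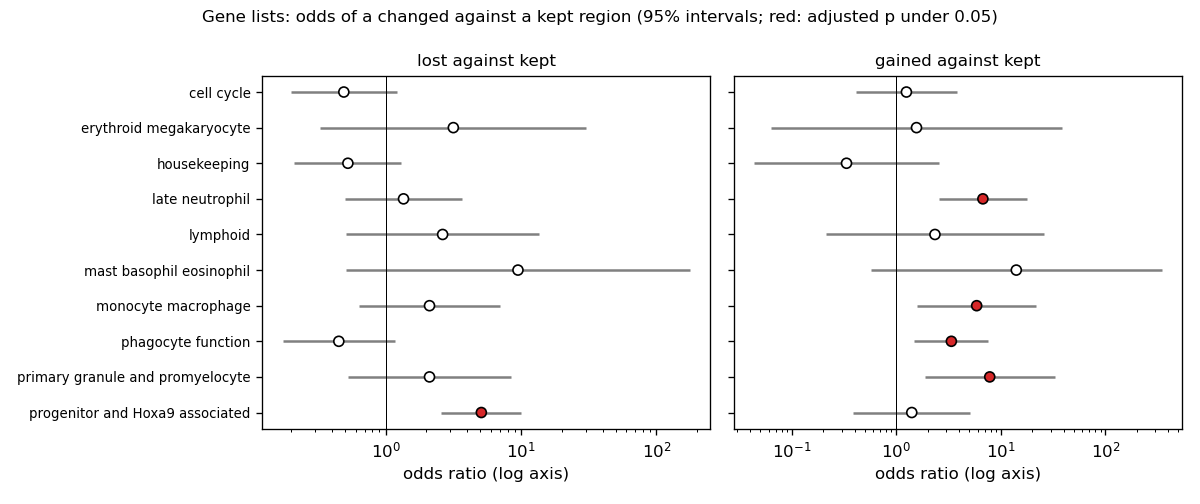
Odds ratio of a lost (left) or gained (right) against a kept region for the 10 fixed gene lists, on a log axis, with 95% intervals as bars and red points for an adjusted p under 0.05. The progenitor list stands at 5.09 for lost regions, and 4 myeloid lists stand between 3.36 and 7.83 for gained regions.

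Over all genes, Zfhx3 had the most lost regions with 8, followed by Auts2 with 7. Cxxc5, Gse1, 2900026A02Rik, Prkag2, Rbm38, Tenm4 and Atp10a had 6 each. The most gained regions were 3, at Pip5k1b, Zswim6, Mtus1, Ptp4a1, Ssh2, Atrnl1, Pid1 and Nfic. Among the genes with 2, H2bc11 and Clasp1 came first by summed width. The widest lost region lay in Pcdh7 (chromosome 5, 57714200 to 57718460, GRCm38), followed by regions in Nr4a2 and Mgat5. The Pcdh7 region was not called after 24 h of withdrawal but was after 40, 56 and 72 h. The widest gained region lay at Jun, an AP-1 subunit gene (chromosome 4, 95050153 to 95053606), followed by Epha7 and Ywhaz. That of Jun was called in every add-back list but that of 56 h, and those of Epha7 and Ywhaz in every list but continuous E2. Among the factors named in advance, Spi1 kept a region at its boundary and lost 1, Cebpe had 1 lost region and Gfi1 had 1 kept region. Cebpa had 1 lost region, at its boundary, and 1 gained region 29079 bases away. Calls of these lost regions were not steady: that of Cebpa was called after 24 and 72 h of withdrawal, and not after 40 or 56 h. The lost region of Cebpe was called after 40 and 56 h, and not after 24 or 72 h.

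Kept regions lay near genes more often than changed ones. Of the kept regions, 72.9% lay within 1000 bases of a gene start or end, against 28.9% of lost regions (odds ratio 0.151, 95% interval 0.140 to 0.163) and 35.2% of gained regions (odds ratio 0.201, interval 0.179 to 0.227). The exact adjusted p for gained regions was 6.74e-159, and that for lost regions was too small for the number format. Neighbouring regions are not independent, so both p-values are smaller than they should be.

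The next comparison asked which end point the cells resembled once E2 was back. At Meis1, the region at the gene boundary (chromosome 11, 19018411 to 19020716) was called in continuous E2 and after 24 and 40 h of withdrawal, and not after 56, 72 or 120 h. Of its other lost regions, 3 were called in continuous E2 alone. The boundary region of Flt3 was called up to 40 h, and that of Mpo, myeloperoxidase, also up to 40 h. In the other direction, gained regions at Fcnb, Ms4a3, Ly6c2, Cd68 and Tlr2 were first called after 72 h, while those at Fpr1, Itgb2l, Ncf1, Ncf4 and Alox5 were called at 120 h alone.

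Lost regions were called in 63.2%, 42.5%, 27.0% and 26.9% of cases after 24, 40, 56 and 72 h of withdrawal with add-back. The difference between 24 and 72 h was -36.3 points (95% interval -37.6 to -35.0), while that between 56 and 72 h was -0.08 points (-0.98 to 0.83). Gained regions were called in 30.5%, 39.7%, 47.6% and 64.1%, a difference of 33.5 points between 24 and 72 h (30.9 to 36.2). Kept regions were called in 92.8%, 92.0%, 91.3% and 94.5%. With all lists cut at random to equal length, the lost share was 21.6 points lower and the gained share 20.7 points higher at 72 than at 24 h. Kept regions also rose, from 64.7% to 78.8%. Random cutting scales the lost shares by the part of each add-back list that is left, and turns kept regions into gained ones. These values are therefore no independent support for the trend. Without narrow peaks the gained difference was 22.1 points. Jaccard indices with continuous E2 were 0.635, 0.518, 0.405 and 0.405, and with 120 h 0.403, 0.50, 0.592 and 0.626. The index between continuous E2 and 120 h was 0.331. Covered bases were 11.5 Mb in continuous E2, 9.20, 7.20, 5.64 and 5.88 Mb in the add-back lists and 4.83 Mb at 120 h. Unequal coverage by itself limits the index, so these indices cannot tell a shift in resemblance from shrinking lists.

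Regions away from gene boundaries stood further apart. There, lost regions were called in 58.7% after 24 h and 16.8% after 72 h, against 74.4% and 51.7% at gene boundaries. Gained regions away from boundaries were called in 16.5% after 24 h and 51.9% after 72 h, against 56.4% and 86.4% at boundaries. This split was chosen after seeing the data.

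**Figure D2:**
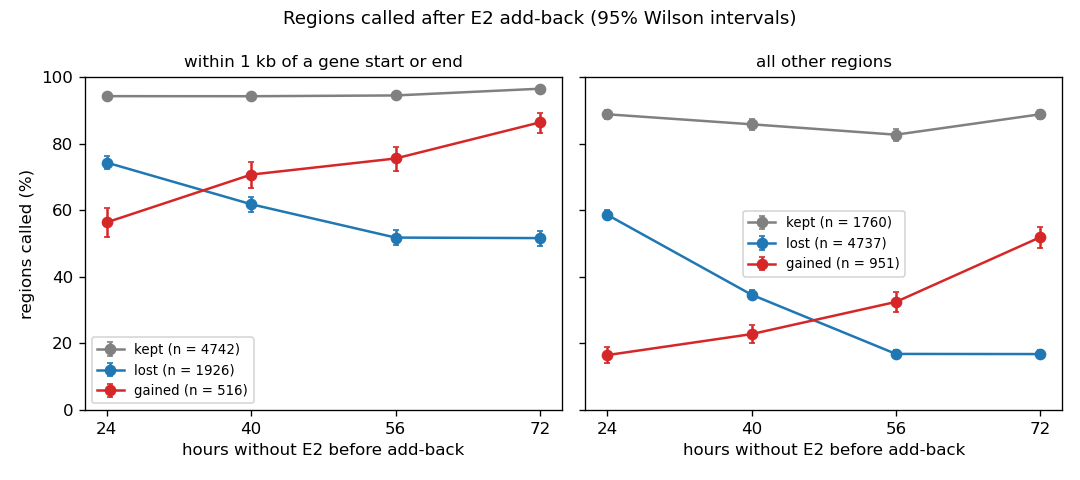
Percent of kept, lost and gained regions called in each add-back list against hours without E2, at gene boundaries (left) and elsewhere (right), with 95% Wilson intervals. Away from boundaries, lost regions went from 58.7% at 24 h to 16.8% at 72 h, and gained regions from 16.5% to 51.9%.

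Of the 48 lost regions of progenitor genes, 36 were called after 24 h, 22 after 40 h, 13 after 56 h and 13 after 72 h. Of the 10 gained regions of late neutrophil genes, 0, 1, 2 and 3 were called, and of the 10 of phagocyte genes 1, 1, 2 and 3. The 5 gained regions of primary granule genes and the 5 of monocyte genes were not called before 72 h, when 3 and 2 were.

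**Figure D3:**
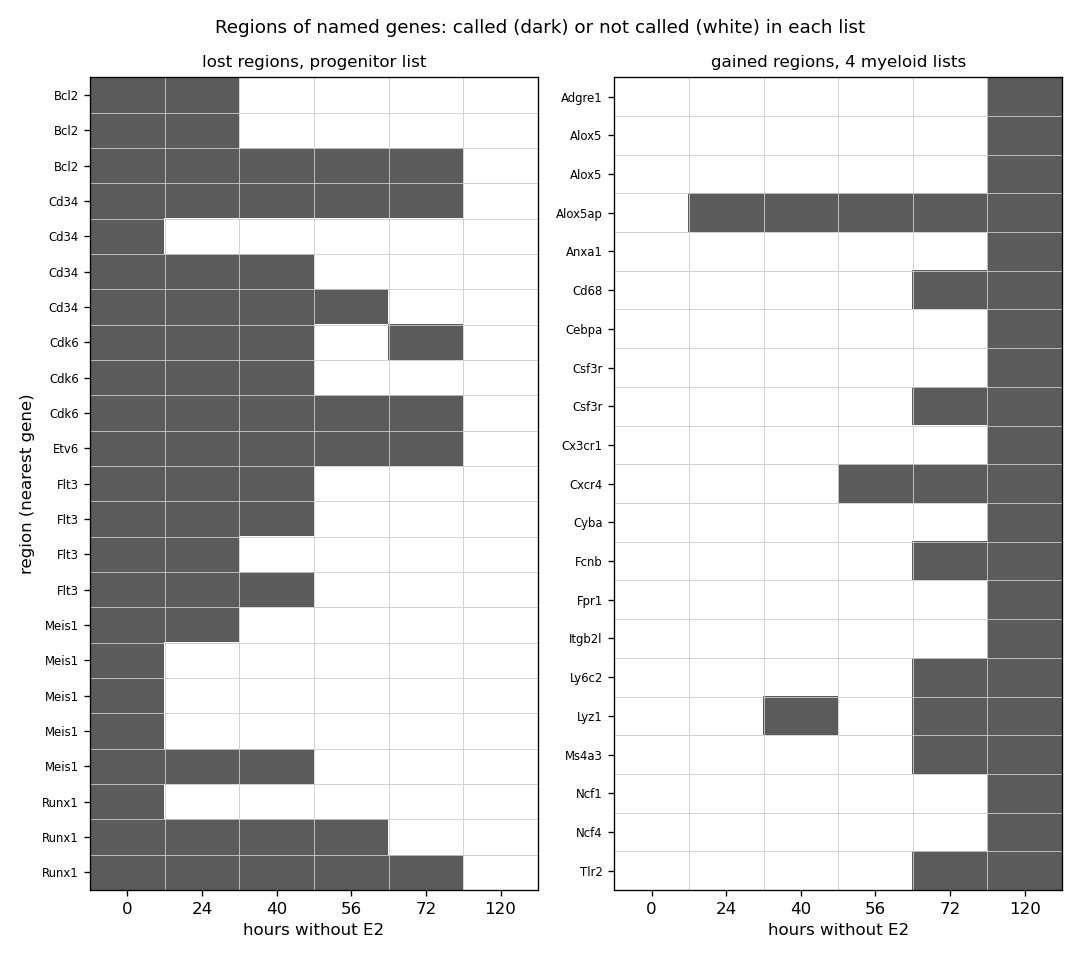
Calls in each list, by hours without E2, for lost regions of named progenitor genes (left) and gained regions of named genes of the 4 myeloid lists (right), with 1 line per region and dark cells for called. The boundary region of Meis1 ends at 40 h, and those of Ms4a3, Ly6c2 and Cd68 start at 72 h.

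The last comparison asked whether single regions switched once along the order of withdrawal. Of the lost regions, 5609 of 6663 did (84.2%), with 1966 missing from 24 h on, 1394 from 40 h, 886 from 56 h, 306 from 72 h and 1057 at 120 h alone. Of the gained regions, 1279 of 1467 did (87.2%), with 319 called from 24 h on and 458 at 120 h alone. Among the 24 orders of the add-back lists, the order of withdrawal gave the highest share for both classes. For lost regions the order with 56 and 72 h exchanged came close, at 83.3%. The lists also shortened, from 11465 peaks at 24 h to 9940 at 40 h and 8989 at 56 h, with 9581 at 72 h. The ranking for lost regions therefore cannot separate withdrawal from list length. All 6 lists shared 5265 regions, the widest of them on chromosome 14 (19415766 to 19419448), with no protein-coding gene within 50000 bases, and in Smarca2 and Mnt. A further 116 regions were called in the 4 add-back lists but at neither end point, the widest in Ppargc1b, Gnas and Gtf3c6, and 54 were called at both end points but in no add-back list, the widest in Atrnl1, Hcfc1 and Macir. As no list from just before add-back was used here, a region called after add-back may have stayed accessible or become so again.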

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

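The tests of repeated entries and of regions missing from 1 list, and the use of the planned gained difference against less sensitive calling, were chosen after the results were seen, while the test of wide peaks was written down before its value was known.

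Intervals of 69.2 to 81.2 Mb, used in no comparison, numbered 16 in the list of 24 h withdrawal against 14 in continuous E2. In both lists, 12 of them lay on chromosome 19 and ended past its last gene at 61.2 Mb. Those 12 are too long to be peaks, so 16 against 14 is not read as a difference between conditions. On chromosomes 18 and 19 lay 26.9% of all continuous-E2 entries before merging and 6.28% after it, inside the range of the other lists, 6.18% to 6.61%, as repeated writing of the same peaks predicts. The upper bound of that share, 6.71%, lies far below 26.9%, but the row counts already fixed this outcome. Of 4546 continuous-E2 entries on these chromosomes, 2530 were exact duplicates, 1175 overlapped another row and 14 were such intervals, which left 827 peaks. The extra entries were therefore repeats, overlaps or long intervals, not further separate sites. A share slightly above the 6.61% of 120 h is not excluded. How the files came to hold these rows stays open, and no biological explanation was tested.

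Regions of continuous E2 that were absent at 120 h, such as those of Meis1 and Cd34, could be weak peaks missed by less sensitive calling. Peaks narrowed with withdrawal even in the 5265 regions of all lists, from a median of 934 bases in continuous E2 to 611 at 120 h, and narrow peaks were lost more often. Of the continuous-E2 peaks in the widest of 10 width classes, those away from gene boundaries were absent at 120 h in 60.5% of cases (95% interval 55.5 to 65.2), above the 20% set in advance as the most that missed weak peaks would leave. At gene boundaries that share was lower, 29.1% in the widest class (26.2 to 32.1) and 21.6% in class 8. Both are nearer the 20%, so the test says less about regions there. Regions missing from the 120 h list alone numbered 1057, against 110 to 319 for each other list. Of these 1057, 59.1% lay at gene boundaries, and missed calls at 120 h would also leave such regions. Calling of gained regions rose by 33.5 points from 24 to 72 h, which less sensitive calling in the 72 h list alone would not allow. That value compares add-back lists, in which kept regions were called about as often (92.8% at 24 h and 94.5% at 72 h). It therefore cannot decide about missed calls at 120 h. Width is a poor stand-in for read depth, so a part of the lost regions may still be missed calls, and the withdrawal of E2 remains an untested biological cause of the rest.

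The regions missing from continuous E2 alone may be chance misses in that list. They numbered 319 (exact Poisson interval 285 to 356), against 236, 224, 234 and 110 missing from a single list of 24, 40, 56 or 72 h, the highest with an upper bound of 268.1. This argues against misses at the rate of the add-back lists as the whole cause. For the part away from gene boundaries, 106 regions (86.8 to 128.2) against at most 88, misses and a gain on first withdrawal cannot be told apart, because the interval includes 88. A higher rate of misses in the continuous E2 list and a gain on withdrawal both stay open as untested.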

How the results depend on the processing

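No paired analysis was possible because 1 list stands for both libraries of each group, although the labels number them 1 and 2. For the same reason no library could be left out. Motif alternatives and those needing a peak score were not run. Leaving out the setting of 200 bases, 8 settings of the overlap, list and chromosome choices were compared. In all of them, calling of lost regions fell from 24 to 56 h and calling of gained regions rose at each step. Random cutting to equal length is no independent support for this, as it thins each add-back list by a different amount. The setting within 200 bases tests nothing, because the lists hold almost no peaks that close, and its unchanged values are no evidence of stability. Main values were 50.6% of continuous-E2 peaks absent at 120 h, 18.4% of 120 h peaks absent in E2, differences of 36.3 (lost) and 33.5 points (gained) and 84.7% of changed regions switching once. In that order, 50% reciprocal overlap gave 58.6, 31.7, 40.3 and 37.4, and peaks at or above the median width of their list 53.4, 23.4, 29.5, 28.0 and 75.5. Equal lengths make the first and second value about equal by construction. By width they gave 38.5, 38.3, 30.2, 26.5 and 80.9, and without narrow peaks the values were 60.5, 11.6, 40.8, 22.1 and 83.8. Equal lengths at random gave 50.5, 21.6, 20.7 and 69.4 from the second value on, and 300 bases around the midpoint gave 52.2 and 21.2 for the first ones. Leaving out peaks by construction removes partners; otherwise the cause was not tested. Leaving out that of 200 bases, of 96 shares called of lost, gained and kept regions 48 stayed inside the main interval. Boundary shares kept their direction and call in every window. Without gene boundary regions, odds ratios were 3.11 (late neutrophil), 2.80 (monocyte), 2.08 (phagocyte) and 7.47 (primary granule) for gained and 2.29 (progenitor) for lost regions, none past the threshold, while fewer lost phagocyte regions passed at 0.126. The primary granule call also ended at equal lengths (5.19) and, chosen after seeing the data, without chromosomes 18 and 19 (6.30). All other gene list calls stayed on their side of the threshold. Unknown depth limits all of these values.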

Other observations

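The shuffles in this part were chosen after the results were seen, while the exact test of progenitor genes away from gene boundaries was planned.

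Gained regions of myeloid genes were called late. Of the 30 gained regions of the late neutrophil, primary granule, monocyte and phagocyte lists, 1 was called after 24 h of withdrawal with add-back. It was that of Alox5ap, which helps make leukotrienes. Of the other gained regions that were assigned to a gene, 33.0% were called. After 72 h, 11 of the 30 were called (36.7%), among them Csf3r, Fcnb, Ms4a3, Ly6c2, Cd68 and Tlr2, against 66.0% of others. In shuffles within gene boundary class, 0 of 10000 gave as few at 24 h (one-sided permutation p = 0.0001, the smallest these shuffles can give) and 29 of 10000 as few at 72 h (permutation p = 0.003). With width matched too, 5 and 45 of 10000 did (permutation p = 0.0006 and 0.0046), which argues against widths and positions alone. A hypothesis is that accessibility at these genes may need E2 to stay away, and that returning E2 holds it back, but no list without add-back at 24 or 72 h was used here to test this.

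The high lost share of progenitor genes might follow from the widths and positions of their regions. In shuffles matched on both, 0 of 10000 reached it, which argues against that. Near gene boundaries, 12 of 16 lost or kept regions were lost, where matched shuffles gave 24.6% on average. Away from them, 36 of 42 were lost (85.7%), where shuffles gave 71.9%, and 266 of 10000 reached the share. The shuffles took regions of the same gene as independent. Over all positions their mean was 58.9%, below the median of 65.5% of random gene lists with the same numbers of regions per gene. The exact test away from boundaries did not pass after adjustment, so an excess there stays open.

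The lists hold almost no neighbouring peaks that are close but separate. Within a list, 2 to 16 gaps were 600 bases or less, while 152 to 379 lay between 1000 and 5000 bases. No continuous-E2 peak without a partner at 120 h lay within 200 bases of one. How the lists were joined or filtered is not given in the sources used here.

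Leaving out chromosome Y, which had 1 region, lost regions made up 43.5% of continuous-E2 regions on chromosome 11, the lowest share, and 56.9% on chromosome 3, the highest.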
